A study of Mus musculus with 46 samples.

How the data were processed

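RNA was sequenced from 46 bulk samples of C57BL/6 mice, 23 from the sciatic nerve and 23 from dorsal root ganglia. Mice were 12 or 36 weeks old and ate a standard diet or a high-fat diet with 45% of its energy from fat, per the labels. The diet and tissue of each library were taken from its listed characteristics, in which samples titled as wild type carry the standard diet. Each of the 8 groups held 6 libraries, except the 36-week standard diet group of each tissue, which held 5. RNA with an integrity number of at least 8 was made into libraries with the TruSeq mRNA v2 kit, which does not mark strand, and sequenced on a HiSeq 2000, per the labels' protocols.

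The deposited values are raw read counts per gene symbol, 1 column per library, with 24062 symbols each. Reads were trimmed with Trimmomatic 0.36, aligned with HISAT2 to the mm10 build and counted with featureCounts, per the submitters' processing notes. The annotation, the strand setting and the treatment of reads shared between genes were not given in the sources used here. Genes that overlap, that lie antisense to another gene or that have near-identical copies are therefore uncertain. Among the genes named, this concerns Cyp2j13, Trim34a, Vmn1r181, Col4a1 with Col4a2, and Itgad, whose coordinates overlap those of the muscle gene Cox6a2 in the RefSeq annotation. Of the symbols, 22550 matched the RefSeq gene table for GRCm38.p6, which gave the coordinates. No value had been normalized, and libraries held between 26.4 and 59 M counts (M, mega).

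All further values were computed from those counts in R 4.3.3. For each tissue, edgeR 4.0.16 was fitted to the 4 groups of age and diet with filterByExpr, TMM factors, robust dispersions and the quasi-likelihood F test. Genes tested numbered 15984 in sciatic nerve, 15977 in dorsal root ganglia and 17223 in a fit of all 8 groups that tested whether the diet difference differed between tissues. Nerve and ganglia libraries were fitted as independent, because the sources used here do not say whether a shared number marks 1 mouse. A gene passed the test when its Benjamini-Hochberg adjusted p within a comparison was under 0.05. All adjusted p values of single genes are from this edgeR test unless another tool is named. Standard errors of log2 fold changes were taken as the fold change divided by the root of the F statistic. Levels are counts per M counts (CPM) on TMM library sizes, given as mean ± SD with n. For a gene with 0 counts in 1 group, fold changes were bounded against a floor of 3 counts over the whole group, and with few counts (1 for Prr32 and Ccl8, 6 for Itgad and 13 for Tph2) the ratio is given with its 95% Poisson interval. Bounds and intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

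There were 10 comparisons, fixed with their tests, gene lists and naming rule before the data were examined. They were the diet difference at each age in each tissue, the difference between ages in that diet difference, the age difference on standard diet, and the difference between tissues in the diet difference at each age. The 36 gene lists comprised 23 of processes and 13 of cell types, with 751 genes, of which 5 were absent. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 36 lists, and again with an estimated correlation and with fry. Members past the test were also counted with p adjusted over the list alone. All list tests were two-sided.

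Genes were named by rule. For the diet comparisons these were the 10 genes with the largest fold change in each direction among those past the test with an average log2 CPM of at least 1, and for the others the 5 in each direction. Up to 4 members with the smallest p were named per list. Where fewer than 3 genes passed, the 5 with the smallest p were named. Genes with predicted names were counted and not named, and a few genes that the rule names are not reported here. Any gene named outside the rule is said to have been chosen after its values were seen.

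The tests were tested on simulated data drawn from the real means and library sizes, with 200 genes changed. In the diet comparison at 36 weeks in sciatic nerve, 76 of 100 genes changed 2-fold and 92 of 100 changed 4-fold were recovered. In the diet comparison at 36 weeks in dorsal root ganglia the numbers were 71 and 97. The simulation gave each gene the same dispersion in all groups, so groups of unlike spread were not simulated. In the diet by age interaction in sciatic nerve they were 42 and 85, and in dorsal root ganglia 51 and 84. Between 4 and 11 unchanged genes were called per comparison. A shift of 0.5 on the log2 scale given to the complement list was called by camera, and none of the other 35 lists was. Simulated genes were drawn independently of one another, so this does not test false list calls among correlated genes. In the real diet comparison at 36 weeks in sciatic nerve, the estimated correlation of the complement list was 0.503.

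Alternatives comprised DESeq2 size factors, upper-quartile factors, no filter and a stricter filter (1 CPM in 5 libraries), a least log2 fold change of 1, DESeq2 1.42.0, limma voom with quality weights, the replicate number as a block, muscle and adipocyte scores as covariates, only the compared groups, both tissues in 1 fit, and each library left out in turn, also for the lists. Calls of named genes lost under settings are counted in the report without the replicate block. After the data were seen, fits without the transcripts Rn45s and Lars2 and fits without 4 libraries in doubt were added. The libraries in doubt were replicates 2 and 4 of the 12-week high-fat diet ganglia, replicate 5 of the 12-week high-fat diet nerve and replicate 4 of the 36-week standard diet nerve. For each comparison, up to 100 splits of the same libraries were refitted. No library was left out of the values in the report.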

Results

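The series measured messenger RNA in 2 peripheral nerve tissues of mice fed a standard or a high-fat diet, a model of type 2 diabetes with neuropathy. Sciatic nerve carries the axons of sensory and motor neurons with their Schwann cells, and dorsal root ganglia hold the cell bodies of sensory neurons with satellite glia. Total counts per library ranged from 31.5 to 59 M in 12-week sciatic nerve on standard diet, 40.4 to 58.1 on high-fat diet, 28.5 to 52.1 at 36 weeks on standard diet and 32.5 to 52.6 on high-fat diet. In dorsal root ganglia the ranges were 30.6 to 50 M, 26.4 to 46.2, 35.8 to 51 and 34.3 to 58.1 in the same order. Each group had 6 libraries, except the 36-week standard diet groups with 5.

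Sciatic nerve libraries differed in the genes of neighbouring tissues. The adipocyte score, the mean log2 CPM of the adipocyte list, was 6.11 ± 0.94 (SD, n = 6) at 12 weeks on standard diet and 5.37 ± 2.36 (n = 6) on high-fat diet, where replicate 5 stood at 0.8. At 36 weeks it was 6.55 ± 0.78 (n = 5) and 7.12 ± 0.18 (n = 6). The skeletal muscle score reached 9.83 in replicate 4 of the 36-week standard diet nerve and 6.89 in replicate 1 of the 12-week standard diet nerve. In ganglia the ribosomal transcript Rn45s took 17.4 ± 12.1% of counts at 12 weeks on high-fat diet and 11.6 ± 3.38% on standard diet (n = 6 each), against 3.82 ± 0.602% (n = 6) and 4.85 ± 1.13% (n = 5) at 36 weeks. Replicate 2 of the 12-week high-fat diet ganglia held 40% Rn45s, and replicate 4 had counts for 13119 genes, the fewest of the 46 libraries.

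**Figure D1:**
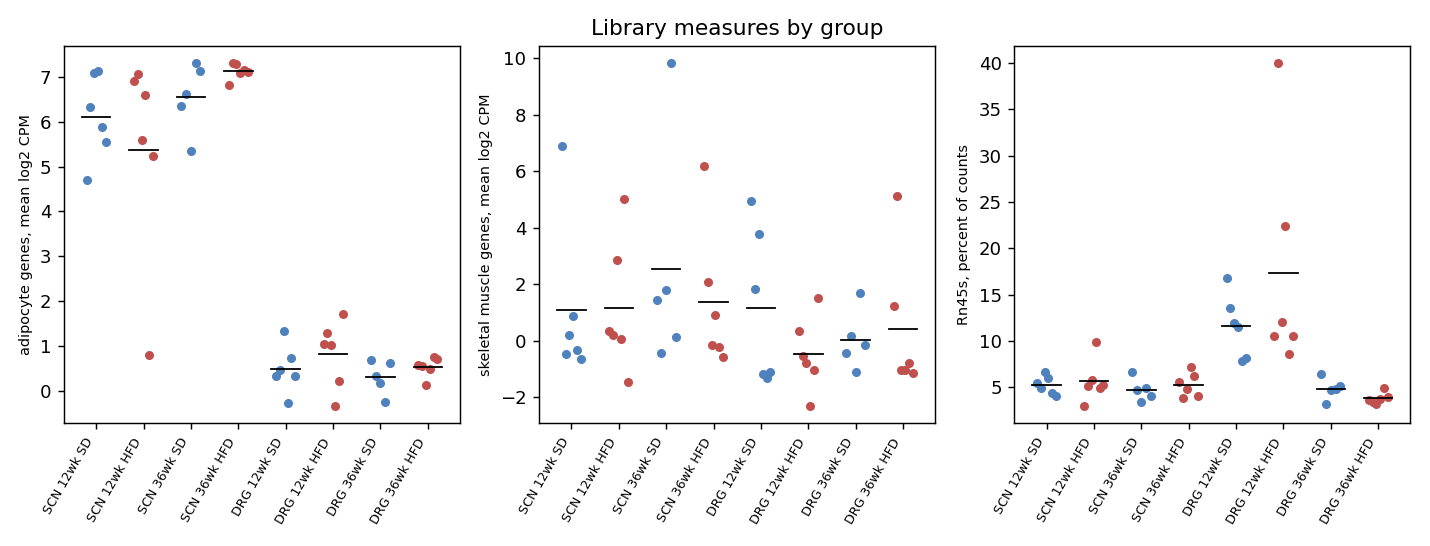
Measures of each library (1 point each) by group, with the group mean as a line: the mean log2 CPM of adipocyte genes, that of skeletal muscle genes, and the percent of counts from Rn45s. 12-week high-fat diet nerve replicate 5 lies at an adipocyte score of 0.8, 36-week standard diet nerve replicate 4 at a muscle score of 9.83, and 12-week high-fat diet ganglia replicate 2 at 40% Rn45s.

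**Figure D2:**
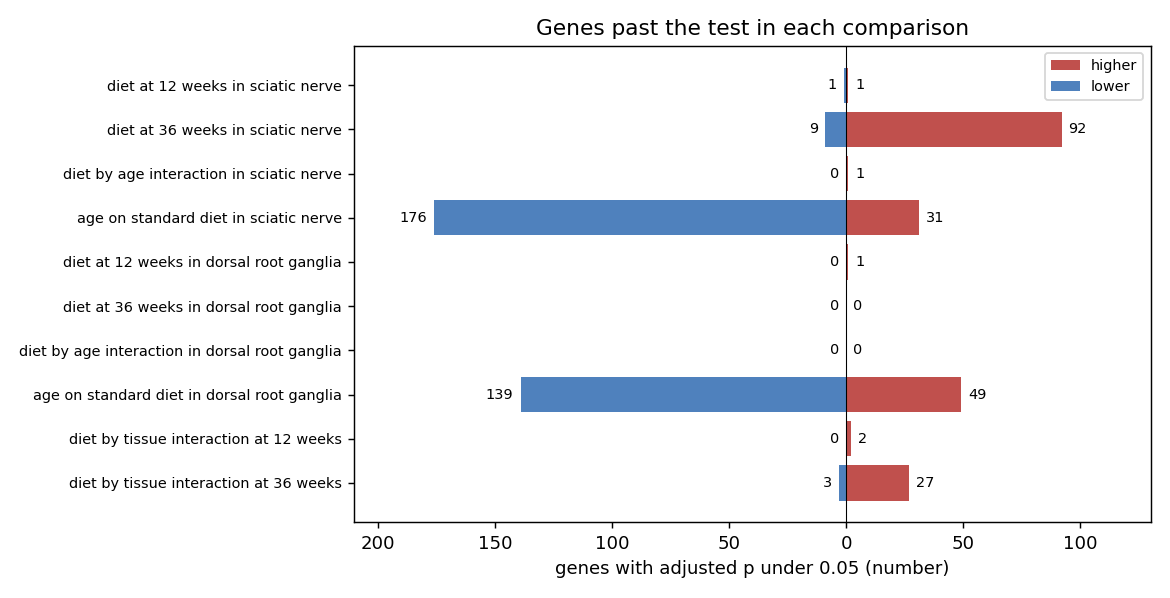
Number of genes past the edgeR test (adjusted p under 0.05) in each of the 10 comparisons, higher to the right and lower to the left of 0. The diet difference at 36 weeks in sciatic nerve had 92 higher and 9 lower genes, and that in dorsal root ganglia had 0.

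The diet comparison at 12 weeks in sciatic nerve asked what the high-fat diet had changed in young mice. Genes that make fatty acids were lower on the high-fat diet. Acaca, the acetyl-CoA carboxylase that commits acetyl-CoA to fatty acid synthesis, fell to 143 ± 16.8 CPM from 251 ± 83.3 (n = 6 each), a log2 fold change of -0.82 (SE 0.14, adjusted p = 0.0271). Prr32 rose from 0 counts in 6 libraries to 650 counts over 6 libraries, at least 218-fold higher (adjusted p = 0.000261). It had 58 to 226 counts in 5 of them and 1 in high-fat diet replicate 5, the library with an adipocyte score of 0.8. The standard diet libraries had 0 counts at adipocyte scores of 4.7 to 7.14. Whether Prr32 came from fat beside the nerve was not tested. Acaca and Prr32 were the only 2 genes past the test, and DESeq2 called 20 and limma voom 3. Of 15984 genes 809 had an unadjusted p under 0.05, about as many as that threshold gives by chance. With only the 2 compared groups in the fit 0 genes passed, as Acaca had an adjusted p of 0.4 and Prr32 had too few libraries with enough counts to be tested.

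Of the 22 tested genes of fatty acid and triglyceride synthesis, 1 fell, 21 did not pass, and 7 fell when adjusted over the list alone. The list had a median log2 fold change of -0.49 with 20 of 22 members negative, and it was lower by camera (adjusted p = 4.53e-18; adjusted p = 0.0198 with an estimated correlation). Fasn, the fatty acid synthase, stood at 415 ± 68.1 against 1070 ± 503 CPM (log2 fold change -1.37, SE 0.25, adjusted p = 0.0593). Acss2 and Acly, which supply acetyl-CoA, had log2 fold changes of -0.9 (SE 0.21) and -0.62 (SE 0.15), each with an adjusted p of 0.268. The adipocyte score of replicate 5 on high-fat diet (0.8) lay below the other 5 high-fat diet libraries (5.24 to 7.07), and adipocytes express the same synthesis genes. Its Fasn level of 410.6 CPM still lay within the range of those other libraries (321.4 to 532.4). Standard diet replicate 4 had the most Fasn (1943 CPM, others 687.7 to 1413), and without it the list median was -0.27 (camera adjusted p = 4.4e-13).

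Some targets of PPAR receptors leaned the other way without passing. Angptl4, an inhibitor of lipoprotein lipase, had a log2 fold change of 1 (SE 0.19, adjusted p = 0.0593). Cpt1a, the carnitine transferase of fatty acid oxidation, had 0.49 (SE 0.11, adjusted p = 0.18). Of the 26 genes of fatty acid oxidation and PPAR targets 0 passed and 3 rose when adjusted over the list alone. The list as a whole did not lean upward, with 10 members positive, 16 negative and a median of -0.06. It was not called by camera (adjusted p = 0.156). Ntrk3, the neurotrophin-3 receptor, had 0.56 (SE 0.11) and Aldh1l1, a folate enzyme of glia, -0.88 (SE 0.16), both with an adjusted p of 0.0593. Slc5a7, the choline transporter, had 4.03 (SE 0.86, adjusted p = 0.187). Its lowest high-fat diet level, 0.583 CPM (others 2.08 to 10.5), was also in replicate 5, the library with few adipocyte genes.

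Camera also called lists whose members did not pass singly. Macrophage genes had a median of -0.43 over 17 members (adjusted p = 2.84e-06; adjusted p = 0.398 with an estimated correlation), with Csf1r at -0.47 (SE 0.23) and Cd163 at -0.57 (SE 0.27). Extracellular matrix genes had a median of -0.2 over 34 (adjusted p = 8.41e-06; adjusted p = 0.398 with an estimated correlation), and fibroblast and perineurium genes -0.21 over 16 (adjusted p = 0.000156; adjusted p = 0.398 with an estimated correlation). Interferon-stimulated genes had 0.39 over 28 (adjusted p = 4.17e-05; adjusted p = 0.421 with an estimated correlation), and complement genes -0.32 over 16 (adjusted p = 0.0032; adjusted p = 0.583 with an estimated correlation). High-fat diet replicate 5, the library with few adipocyte genes, also had the lowest mean log2 CPM of macrophage genes (1.87, others 3.19 to 4.27), matrix genes (6.91, others 7.66 to 8.27) and fibroblast genes (5.43, others 6.77 to 7.55). Without it the medians were -0.25, -0.11 and -0.08 (adjusted p = 0.00262, 0.00262 and 0.0163), and complement genes lost their call (0.179). Interferon-stimulated genes lost theirs without high-fat diet replicate 2 (median 0.06, adjusted p = 0.129), and the fibroblast median was -0.37 and -0.33 without replicates 1 and 2. Camera called 3 more lists higher, with adjusted p values of 0.398, 0.77 and 0.0667 with an estimated correlation. They were nonmyelinating Schwann cell genes (median 0.24 over 11, camera adjusted p = 0.00227), myelin genes (0.12 over 22, 0.0131) and spinal cord genes (0.94 over 6, 0.00501). Myelin genes lost their call without high-fat diet replicate 5 (median 0.04, camera adjusted p = 0.881).

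Acaca also lost its call with a log2 fold of at least 1, by limma voom (adjusted p = 0.0509), without the libraries in doubt (0.0985), without standard diet replicate 1 (0.0574) or 3 (0.0963), and without high-fat diet replicate 3 (0.134), 4 (0.14), 5 (0.0596) or 6 (0.0566). The count was 1 without standard diet replicate 1 or 3 or high-fat diet replicate 3 or 4, 4 without standard diet replicate 2 or high-fat diet replicate 1 or 5, 5 without standard diet replicate 6 and 8 without high-fat diet replicate 2.

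The diet comparison at 36 weeks in sciatic nerve asked the same of older mice. On the high-fat diet 92 genes rose and 9 fell, and 1454 of 15984 had an unadjusted p under 0.05. Integrins of macrophages and dendritic cells were among the largest rises. Itgad, the integrin alpha D chain, went from 0.0414 ± 0.0926 (n = 5) to 46.3 ± 15.7 CPM (n = 6), with 11418 counts against 6, all in 1 library, a ratio of 1570 (95% counting interval 722 to 4280, adjusted p = 0.00234). Itgax, the CD11c chain, went from 1.85 ± 0.715 to 9.96 ± 3.5 CPM (log2 fold change 2.43, SE 0.54, adjusted p = 0.0245). Mmp12, the macrophage elastase, went from 0.609 ± 0.416 to 32.8 ± 14.9 CPM (5.75, SE 1.3, adjusted p = 0.0462).

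Other large rises were in single genes. Tph2, a serotonin-making hydroxylase, had 13 counts over 5 standard diet libraries and 9084 over 6 high-fat diet libraries, a ratio of 577 (interval 337 to 1080, adjusted p = 0.00173). Slc5a7, the choline transporter, rose by 5.79 on the log2 scale (SE 0.96) and Oxtr, the oxytocin receptor, by 4.13 (SE 0.51), from 4.98 ± 1.68 to 87.6 ± 34.4 CPM (adjusted p = 0.00402 and 0.000201). Slc5a7 was listed as a spinal cord marker, and it was the only 1 of the 6 tested genes of that list to pass. Mest, an imprinted gene of expanding fat, rose by 2.94 (SE 0.49), Cela1, an elastase, by 1.92 (SE 0.31) and Lpgat1, an acyltransferase of phosphatidylglycerol, by 1.79 (SE 0.37). The smallest adjusted p was that of Serpina3n, a protease inhibitor (log2 fold change 1, SE 0.118, adjusted p = 3.84e-05), which was chosen after its values were seen.

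Among the 9 genes that fell was Acsm3, a medium-chain acyl-CoA synthetase, by 4.87 (SE 0.91, adjusted p = 0.0122). Also lower were the phosphatase subunit gene Ppp2r2c by 1.28 (SE 0.29) and Sytl2 by 0.92 (SE 0.21). The transcription factor genes Sox6 and Creb1 fell by 0.71 (SE 0.16) and 0.49 (SE 0.1), and the transcription termination gene Pcf11 by 0.48 (SE 0.1). Stmn4, of the stathmin family of microtubule regulators, fell by 3.58 (SE 0.83, adjusted p = 0.0322) and was the 1 member of the 22 tested in the neuronal injury and regeneration list to pass.

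Few members of each list passed. Of 26 genes of fatty acid oxidation and PPAR targets, Angptl4 rose from 110 ± 6.12 to 250 ± 40.4 CPM (log2 fold change 1.18, SE 0.2, adjusted p = 0.00334), 25 did not pass, and 5 rose when adjusted over the list alone. That list was higher by camera (adjusted p = 7.94e-06; adjusted p = 0.43 with an estimated correlation). Of 24 antioxidant genes, 2 rose, the extracellular superoxide dismutase Sod3 by 0.9 (SE 0.15) and the peroxiredoxin Prdx6 by 0.45 (SE 0.09), with 4 over the list alone and no call by camera (adjusted p = 0.222). Of 34 extracellular matrix genes, the basement membrane collagens Col4a1 and Col4a2 rose by 0.42 (SE 0.07) and 0.43 (SE 0.08), with 5 higher and 1 lower over the list alone (camera adjusted p = 0.00759; adjusted p = 0.729 with an estimated correlation). Of 24 cholesterol synthesis genes, Insig1, which holds back the sterol-sensing factor, rose by 0.43 (SE 0.09), with 2 over the list alone (camera adjusted p = 0.0237; adjusted p = 0.749 with an estimated correlation). B2m, the light chain of class I molecules, rose by 0.52 (SE 0.11), as 1 of 17 antigen presentation genes (camera adjusted p = 0.00317; adjusted p = 0.687 with an estimated correlation). Pfkl, a phosphofructokinase, rose by 0.59 (SE 0.12), as 1 of 22 glycolysis and polyol genes (camera adjusted p = 0.601).

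Adipocyte genes moved apart from one another. Lep, the adipokine leptin, stood at 756 ± 210 against 48.7 ± 38.7 CPM (log2 fold change 3.95, SE 0.97, adjusted p = 0.0799) and Dgat2, of triglyceride synthesis, at 666 ± 108 against 193 ± 99.3 (1.79, SE 0.54, adjusted p = 0.22). Cfd, the adipokine adipsin, stood at 356 ± 137 against 1700 ± 627 (-2.25, SE 0.7, adjusted p = 0.24). Of 20 adipocyte genes 0 passed, and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0156; adjusted p = 0.77 with an estimated correlation). Skeletal muscle genes had a median log2 fold change of -3.84 over 20 members with 0 past the test (camera adjusted p = 0.0205; adjusted p = 0.85 with an estimated correlation), and the muscle score was 9.83 in 1 of the 5 standard diet libraries. Cell cycle genes had a median of 0.35 over 32 (adjusted p = 0.00341; adjusted p = 0.43 with an estimated correlation), and pericyte and smooth muscle genes -0.56 over 14 (adjusted p = 0.0028; adjusted p = 0.687 with an estimated correlation).

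Of the 34 genes named here or in the closing section as past the test in this comparison, 23 passed with any 1 library left out. Mmp12 passed in 1 of 11 such fits (highest adjusted p 0.133, without standard diet replicate 2) and Itgax in 4 of 11 (0.0812, without the same library). The others that lost a call were Lpgat1, Ppp2r2c, Sytl2, Sox6, Creb1, Insig1, Pfkl, B2m and Stmn4. Without standard diet replicates 1, 2, 3, 4 and 5, the named genes that lost a call numbered 7, 9, 5, 6 and 5 (adjusted p up to 0.13, 0.133, 0.101, 0.102 and 0.108). Without high-fat diet replicates 1, 2, 3, 4, 5 and 6 they numbered 4, 8, 4, 3, 6 and 5 (adjusted p up to 0.0792, 0.107, 0.0729, 0.0701, 0.0864 and 0.0759). The count was 61 without high-fat diet replicate 2 and 64 without standard diet replicate 1. With a log2 fold of at least 1, 17 of the 34 lost a call. Under settings of normalization, filter, test, covariate or libraries in the fit 10 did, namely Mmp12, Acsm3, Sytl2 and Stmn4 by limma voom (adjusted p up to 0.117), Itgax, Insig1, B2m, Col4a1 and Col4a2 with both tissues in 1 fit (up to 0.196), and Sox6 and Stmn4 with only the compared groups (up to 0.0594). Among the lists, cholesterol genes lost their call in 4 of 11 fits with 1 library left out, matrix and adipocyte genes without standard diet replicate 3 (0.0555 and 0.264), and muscle genes in 4, turning positive without standard diet replicate 4 (median 2.58, adjusted p = 0.122) and at -6.41 without high-fat diet replicate 1. Without the same standard diet replicate 4 the pericyte median was -0.27 (adjusted p = 0.0463), and without standard diet replicate 3 that of antigen presentation genes was 0.15 against 0.26 (adjusted p = 0.033).

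**Figure D3:**
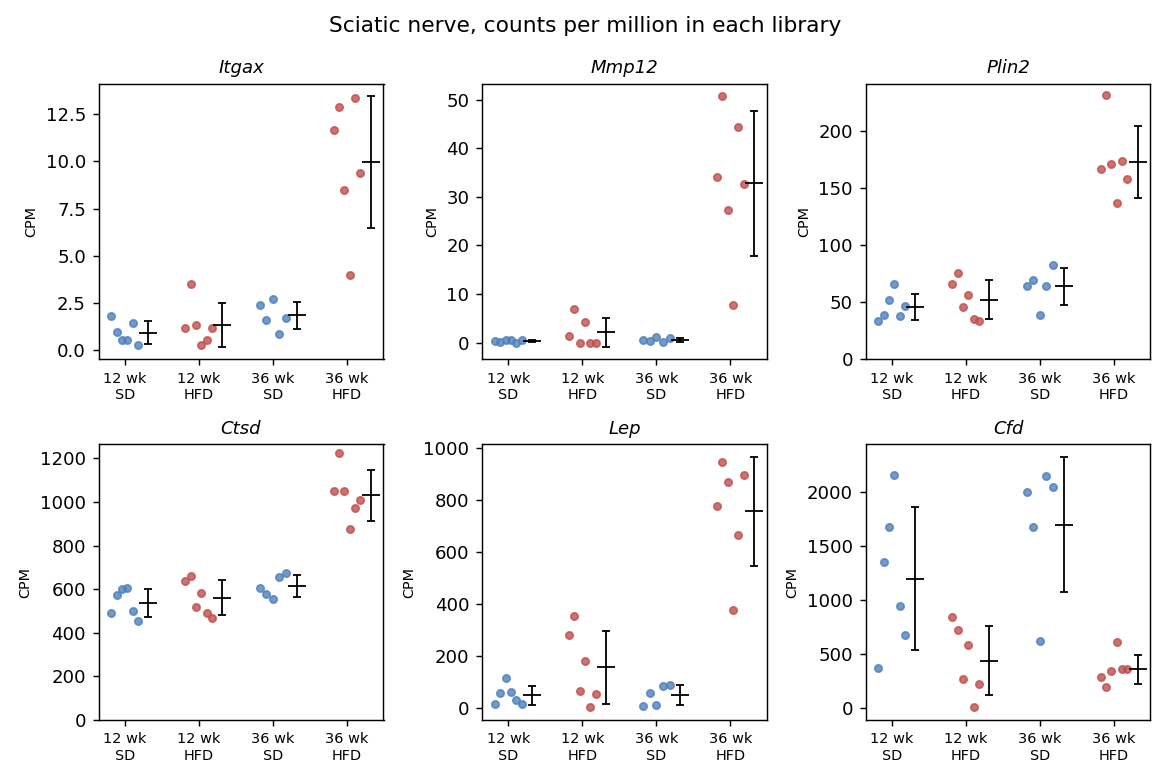
CPM of 6 genes in each sciatic nerve library (points), with the mean and SD of each group (bars; n = 6, and 5 at 36 weeks on standard diet); the genes were chosen after their values were seen. Lep averaged 756 CPM at 36 weeks on high-fat diet against 48.7 on standard diet, and Cfd 356 against 1700.

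Prr32, the single gene higher at 12 weeks, was also among the 92 genes higher at 36 weeks, where chance gives 0.00576 shared genes. At 36 weeks it had 1227 counts in high-fat diet nerve and 1 in standard diet nerve, a ratio of 1010 (interval 182 to 40100), and was named there after its values were seen. Of the 92 genes, 73 had a positive log2 fold change at 12 weeks. Across 12817 genes, which are not independent replicates, the fold changes at both ages had a Pearson r of 0.383 and a Spearman rho of 0.06.

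The diet by age interaction in sciatic nerve tested whether the diet difference changed between ages. The group labels hold no length of feeding, so age and time on the diet cannot be told apart in such a change. Pgd, a dehydrogenase of the pentose phosphate pathway that yields NADPH, was the only gene past the test. On the high-fat diet it stood at 78.8 ± 10.9 against 96.2 ± 13.5 CPM at 12 weeks (n = 6 each) and at 143 ± 17.1 (n = 6) against 92.9 ± 11.6 (n = 5) at 36 weeks, a log2 difference of 0.91 (SE 0.15, adjusted p = 0.0269). Below the threshold came Htra1, a secreted protease (0.89, SE 0.17), Ctsd, the lysosomal cathepsin D (0.69, SE 0.14), Fam20c, a kinase of secreted proteins (1.06, SE 0.21), and Ntrk3 (-0.78, SE 0.16), each with an adjusted p of 0.0837. Insig1 had 0.56 (SE 0.13) and Col4a2 0.48 (SE 0.11), both with an adjusted p of 0.132. An unadjusted p under 0.05 was found for 979 genes, and DESeq2 called 33 and limma voom 8.

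Camera called the interaction in most of the 36 lists, all without a member past the test, and some of them are given here. Extracellular matrix genes had a median of 0.31 over 34 members (adjusted p = 1.94e-07; adjusted p = 0.327 with an estimated correlation), fatty acid and triglyceride synthesis 0.34 over 22 (adjusted p = 1.06e-06; adjusted p = 0.327 with an estimated correlation) and macrophage genes 0.61 over 17 (adjusted p = 7.28e-06; adjusted p = 0.44 with an estimated correlation). Cytokines and chemokines had 0.72 over 26 (adjusted p = 1.03e-05; adjusted p = 0.312 with an estimated correlation). Their median was 0.4 without 12-week standard diet replicate 6, 0.43 and 1.12 without 36-week standard diet replicates 2 and 1, and 0.47 without 36-week high-fat diet replicate 1. The fatty acid synthesis median was 0.22 without 12-week standard diet replicate 4. Lists of cell markers were called too at the preset correlation, adipocyte genes with a median of 0.66 (camera adjusted p = 0.000527) and fibroblast and perineurium genes with 0.25 (0.0171). Nonmyelinating Schwann cell genes had -0.39 (camera adjusted p = 0.000551) and myelin genes -0.16 (0.0204). With 1 library left out, fibroblast genes lost their call in 2 of 23 fits and myelin genes in 6. Without 12-week high-fat diet replicate 5, the library with few adipocyte genes, the adipocyte median was 0.42 (camera adjusted p = 0.0381). The fibroblast median was then 0.13, without a call (camera adjusted p = 0.18).

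Pgd passed in 11 of 23 fits with 1 library left out. Its adjusted p was 0.0507, 0.083, 0.0745 and 0.0538 without 12-week standard diet replicates 2, 3, 4 and 5, and 0.0524, 0.0635 and 0.0719 without 12-week high-fat diet replicates 3, 4 and 6. It was 0.105, 0.0814, 0.0763 and 0.0555 without 36-week standard diet replicates 1, 2, 3 and 4, and 0.0739 without 36-week high-fat diet replicate 2. In each of these fits 0 genes were called, and the count was 14 and 13 without 12-week high-fat diet replicates 2 and 1, 7 without 36-week high-fat diet replicate 4 and 5 without 12-week standard diet replicate 6. Pgd also lost its call without the libraries in doubt (0.0892) and with a log2 fold of at least 1.

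The age comparison on standard diet in sciatic nerve described the difference between 12 and 36 weeks without the high-fat diet. Genes of cholesterol synthesis fell together. Mvd, the mevalonate diphosphate decarboxylase of that pathway (chromosome 8, 122433596 to 122443422, GRCm38.p6), fell from 32.7 ± 6.93 (n = 6) to 9.15 ± 2.15 CPM (n = 5), by 1.84 on the log2 scale (SE 0.19, adjusted p = 5.35e-07). In all 176 genes fell and 31 rose, with 1591 at an unadjusted p under 0.05. Of the 24 cholesterol genes, 21 fell, 3 did not pass, and 22 fell when adjusted over the list alone. Their median was -1.05 (camera adjusted p = 4.14e-120; adjusted p = 5.44e-06 with an estimated correlation), and among the other members Hmgcs1 fell by 1.12 (SE 0.12) and Sc5d by 1 (SE 0.1). The score of these 24 genes, their mean log2 CPM, was 6.44 ± 0.18 at 12 weeks and 5.4 ± 0.17 at 36 weeks (two-sided exact permutation p = 0.00216, n = 6 and 5).

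Genes of the myelin sheath fell as well. Of 22 tested, 8 fell, 14 did not pass, and 13 fell over the list alone. Pmp22, a protein of compact myelin, fell from 19000 ± 2830 to 9960 ± 1660 CPM (log2 fold change -0.93, SE 0.16, adjusted p = 0.00188). Pmp2, its fatty acid binding protein, fell by 1.01 (SE 0.14), Ugt8a, which makes galactosylceramide, by 0.92 (SE 0.15) and Fa2h, which hydroxylates myelin lipids, by 0.95 (SE 0.16). The list was lower by camera (adjusted p = 3.86e-26; adjusted p = 0.0969 with an estimated correlation). Of 22 fatty acid and triglyceride synthesis genes 4 fell, among them Elovl6 by 0.89 (SE 0.14), Fads2 by 0.73 (SE 0.12) and Acss2 by 0.99 (SE 0.22), with 8 over the list alone (camera adjusted p = 8.65e-05; adjusted p = 0.316 with an estimated correlation). The median of that list was -0.03, and -0.23 to 0.07 with 1 library left out.

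Matrix genes fell in part. Of 34 tested, 7 fell, with 10 lower and 1 higher over the list alone. Lox, which cross-links collagen, fell from 930 ± 125 to 362 ± 44.6 CPM (log2 fold change -1.36, SE 0.12, adjusted p = 1.4e-07). Col4a1 and Col4a2 each fell by 0.55 (SE 0.07 and 0.08) and Sparc by 0.49 (SE 0.08). The list was lower by camera (adjusted p = 2e-06; adjusted p = 0.347 with an estimated correlation).

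Targets of glucocorticoids fell, 7 of 19 tested and 10 over the list alone, with 1 higher over the list alone (camera adjusted p = 1.71e-12; adjusted p = 0.00569 with an estimated correlation). Tsc22d3, the leucine zipper induced by glucocorticoids, fell by 1.03 (SE 0.16), Klf15 by 0.71 (SE 0.1), and the metallothioneins Mt2 and Mt1 by 1.69 (SE 0.3) and 1.08 (SE 0.23). Of 19 clock genes 6 fell, with 8 lower and 2 higher over the list alone (camera adjusted p = 0.000195; adjusted p = 0.121 with an estimated correlation), with a median of -0.22, and -0.09 without 12-week replicate 6. Dbp, an output of the clock, fell from 150 ± 27 to 85.6 ± 21.5 CPM (log2 fold change -0.8, SE 0.14), Ciart by 1.54 (SE 0.38) and Per2 by 0.76 (SE 0.19). The time of day of collection was not given in the sources used here.

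Genes of the unfolded protein response rose, 5 of 23 tested and 7 over the list alone (camera adjusted p = 2e-06; adjusted p = 0.0208 with an estimated correlation). The chaperone Hspa5 rose by 0.51 (SE 0.1), Manf by 0.56 (SE 0.11), Creld2 by 0.67 (SE 0.14) and the transcription factor gene Xbp1 by 0.38 (SE 0.09). Single members of other lists rose, namely Mpeg1, a macrophage perforin, by 1.28 (SE 0.31), Rtp4, induced by interferon, by 0.99 (SE 0.25), the chemokine gene Cxcl12 by 0.39 (SE 0.09) and the chaperone Hspa8 by 0.36 (SE 0.08). Macrophage genes had a median of 0.42 over 17 (camera adjusted p = 1.49e-05; adjusted p = 0.355 with an estimated correlation). Interferon-stimulated genes had 0.49 over 28 (camera adjusted p = 1.49e-05; adjusted p = 0.347 with an estimated correlation), and 0.29 without 36-week replicate 5 (camera adjusted p = 0.0146).

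The largest rises were in Ppp2r2c by 1.42 (SE 0.29), Chd5, a chromatin remodeller of neurons, by 1.38 (SE 0.25), Slc6a2, the noradrenaline transporter, by 1.37 (SE 0.33), Mpeg1, and Trim34a by 1.11 (SE 0.27). Among the largest falls beside Mvd were those in Cyp2j13 by 2.09 (SE 0.35), the sodium channel subunit gene Scn3b by 1.75 (SE 0.21) and Hif3a by 1.72 (SE 0.29). Skeletal muscle genes had a median of 3.17 over 20 with 0 past the test (camera adjusted p = 0.0209; adjusted p = 0.751 with an estimated correlation). The muscle score was 9.83 in 1 of 5 libraries at 36 weeks and 6.89 in 1 of 6 at 12 weeks. Of the 36 named genes that passed, 25 passed with any 1 library left out. The other 11 were Slc6a2, Mpeg1, Trim34a, Acss2, Xbp1, Mt1, Ciart, Per2, Hspa8, Cxcl12 and Rtp4. Without 12-week replicates 1, 2, 3, 4, 5 and 6, those lost numbered 5, 4, 2, 4, 7 and 6 (adjusted p up to 0.0982, 0.121, 0.0785, 0.0926, 0.093 and 0.104). Without 36-week replicates 1, 2, 3, 4 and 5 they numbered 8, 7, 3, 5 and 9 (adjusted p up to 0.0822, 0.142, 0.063, 0.0766 and 0.215), and the count was 133 without 36-week replicate 5. With a log2 fold of at least 1, 19 of the 36 lost a call. Under settings of normalization, filter, test, covariate or libraries in the fit 10 did, among them Slc6a2, Trim34a, Acss2, Ciart, Per2 and Cxcl12 with only the compared groups (adjusted p up to 0.269) and Slc6a2, Trim34a, Xbp1, Sparc, Ciart, Cxcl12 and Rtp4 with both tissues in 1 fit (up to 0.41). Muscle genes lost their call in 5 of 11 fits with 1 library left out, turning negative without 36-week replicate 4 (median -3.16, adjusted p = 0.0865) and at 7.01 without 12-week replicate 1.

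**Figure D4:**
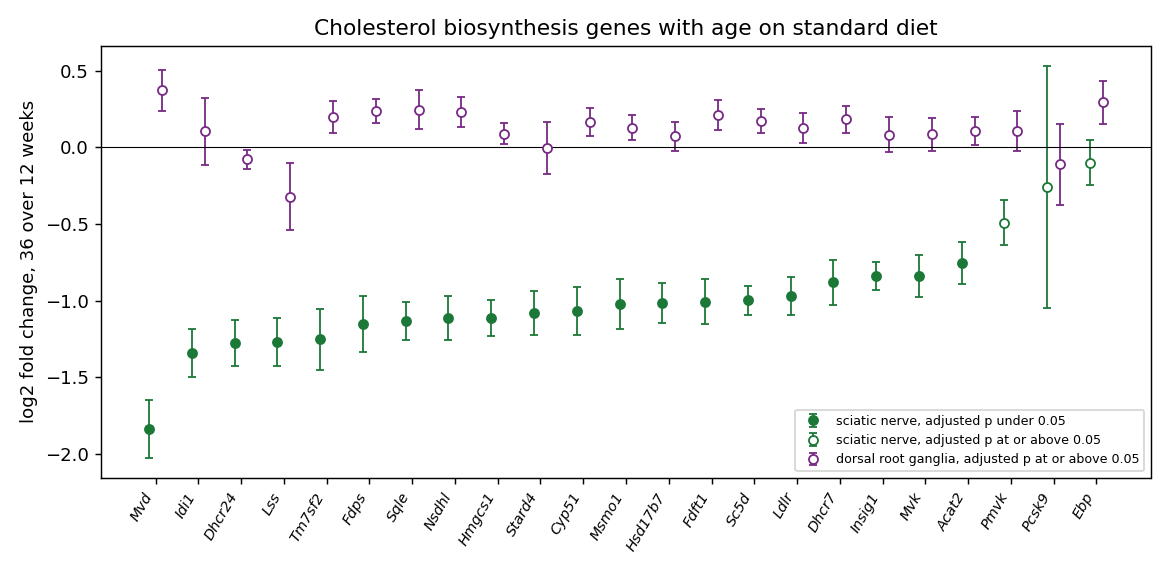
Log2 fold change (36 over 12 weeks, standard diet) with its standard error for 23 of the 24 genes of the cholesterol synthesis list, in sciatic nerve and in dorsal root ganglia; filled points passed the edgeR test. Over the whole list, 21 genes passed in sciatic nerve, all lower, with a median of -1.05, and 0 passed in dorsal root ganglia, with a median of 0.12.

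The diet comparison at 12 weeks in dorsal root ganglia found 1 gene past the edgeR test, which has a predicted name and went from 1 count to 267. An unadjusted p under 0.05 was found for 1120 genes, and DESeq2 called 29 and limma voom 0. Genes with the smallest p were mostly at the edge of detection. Cd68, a lysosomal marker of macrophages, stood at 3.12 ± 2.03 against 0.638 ± 0.215 CPM (n = 6 each, log2 fold change 2.28, SE 0.49, adjusted p = 0.296) and Ppard, a PPAR receptor, at 20.6 ± 8 against 11.6 ± 2.31 (0.83, SE 0.19, adjusted p = 0.337). Gpr141 stood at 0.00456 ± 0.0112 against 0.589 ± 0.432 CPM (adjusted p = 0.234) and Lsmem1 at 0.029 ± 0.0359 against 0.78 ± 0.304 (adjusted p = 0.296). Vmn1r181, a vomeronasal receptor, was at 0 in the 6 high-fat diet libraries and at 0.492 ± 0.675 CPM on standard diet (adjusted p = 0.296).

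Camera called 5 lists here, each with 0 members past the test and an adjusted p of 0.94 with an estimated correlation. Skeletal muscle genes had a median of -3.43 over 20 (adjusted p = 0.00262), myelin genes 0.15 over 22 (adjusted p = 0.00696) and neuronal injury genes 0.17 over 24 (adjusted p = 0.0291). Fatty acid oxidation genes had 0.08 over 25 and oxidative phosphorylation genes 0.05 over 41 (adjusted p = 0.0297 each). The muscle score was -0.48 ± 1.3 on high-fat diet and 1.16 ± 2.78 on standard diet, and Rn45s took 17.4 ± 12.1% and 11.6 ± 3.38% of counts (n = 6 each). The count was 0 without standard diet replicate 1, 2, 3, 4, 5 or 6 or high-fat diet replicate 4, and 2 without high-fat diet replicate 2. The lists lost their call in 1 (muscle), 3 (myelin), 5 (neuronal injury), 4 (fatty acid oxidation) and 6 (oxidative phosphorylation) of 12 fits with 1 library left out, where their weakest medians were -1.53, 0.06, 0.05, 0.04 and -0.02.

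The diet comparison at 36 weeks in dorsal root ganglia called 0 genes by edgeR, with 158 of 15977 at an unadjusted p under 0.05, 0 by DESeq2 and 21 by limma voom. These 158 are fewer than a threshold of 0.05 gives by chance, so the edgeR p values ran high here. The 0 calls therefore do not show that the diet had no effect. Atf3, a transcription factor induced in injured sensory neurons, stood at 13.5 ± 7.47 (n = 6) against 40.6 ± 32.1 CPM (n = 5), a log2 fold change of -1.59 (SE 0.45). On standard diet Atf3 was at 56.9 and 89.6 CPM in replicates 1 and 2 and at 15.6 to 23.1 in the other 3, near the 7.44 to 27.9 of the high-fat diet libraries. Kcnip2, a potassium channel subunit gene, had 0.32 (SE 0.09), Smim3 -0.82 (SE 0.23), the matrix gene Postn -0.68 (SE 0.2) and Kcnj10, a potassium channel of satellite glia, -0.37 (SE 0.11). The adjusted p of each of these genes was 1.

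Of 24 neuronal injury and regeneration genes 22 had a negative fold change, 0 passed and 2 fell over the list alone, with a median of -0.4 (camera adjusted p = 1.04e-15; adjusted p = 0.0876 with an estimated correlation). Antigen presentation genes had a median of -0.32 with 17 of 17 negative (camera adjusted p = 1.83e-09; adjusted p = 0.153 with an estimated correlation). Interferon-stimulated genes had -0.22 with 25 of 28 negative (camera adjusted p = 1.83e-09; adjusted p = 0.133 with an estimated correlation). Myelin genes had -0.15 with 17 of 22 negative (camera adjusted p = 0.00114; adjusted p = 0.599 with an estimated correlation). Skeletal muscle genes had a median of 2.87 with 19 of 20 positive (camera adjusted p = 0.00614; adjusted p = 0.717 with an estimated correlation), and the muscle score was 0.4 ± 2.49 on high-fat diet (n = 6) and 0.03 ± 1.04 on standard diet (n = 5). The count was 0 without any 1 of the 11 libraries.

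A few standard diet libraries carried part of these list differences. The mean log2 CPM of the neuronal injury genes was 5.32 and 5.11 in standard diet replicates 1 and 2, 4.14 to 4.63 in the other 3 and 4.1 to 4.47 on high-fat diet. Among the members, Sprr1a had 9.2 ± 13.1 CPM (0.127 to 31.8) on standard diet and Ecel1 5.25 ± 5.47 (1.22 to 14.8), and the interferon-stimulated Gbp2 had 24.7 ± 27.8 (6.06 to 73.2). Without replicate 2 the injury median was -0.27 (camera adjusted p = 1.12e-07; adjusted p = 0.201 with an estimated correlation). Interferon-stimulated genes were at 2.94, 3.18 and 3.02 in standard diet replicates 1, 4 and 5 and at 2.05 to 2.71 in the other 8 libraries, and their median was -0.4 without standard diet replicate 3. Myelin genes lost their call in 3 of 11 fits with 1 library left out (adjusted p up to 0.512, medians from -0.33 to -0.03) and muscle genes in 2, turning negative without high-fat diet replicate 2 (median -0.53, adjusted p = 0.0466).

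The diet by age interaction in dorsal root ganglia called 0 genes by edgeR, with 519 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma voom. These 519 of 15977 are also fewer than a threshold of 0.05 gives by chance, so 0 calls do not show an equal diet response at both ages. The smallest p belonged to Creb3l1, a transcription factor gene of the secretory pathway (log2 difference 1, SE 0.23), Kcnj2, a potassium channel gene (2.19, SE 0.54), Vmn1r181, and the muscle genes Myom2 (6.23, SE 1.6) and Cox6a2 (7.38, SE 1.95), each with an adjusted p of 1. Vmn1r181 was at 0 in the 12-week high-fat diet libraries, so that no fold is given. Skeletal muscle genes had a median of 6.45 over 20 with 0 past the test and 16 higher over the list alone (camera adjusted p = 7.06e-06, and not called with an estimated correlation). That median was 2.08 without 36-week high-fat diet replicate 2 (camera adjusted p = 0.00409) and 4.17 without 12-week standard diet replicate 1 (camera adjusted p = 0.0158). Neuronal injury genes had -0.57 over 24 (camera adjusted p = 4.58e-10; adjusted p = 0.404 with an estimated correlation).

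The age comparison on standard diet in dorsal root ganglia found 139 genes lower and 49 higher at 36 weeks, with 2126 at an unadjusted p under 0.05. More genes passed without the ganglia libraries in doubt, which are on high-fat diet and enter this comparison only through the shared fit. Collagens and matrix enzymes fell. Lox fell from 27.4 ± 5.84 (n = 6) to 8.4 ± 1.13 CPM (n = 5), by 1.71 on the log2 scale (SE 0.28, adjusted p = 0.00557), Col5a1 by 1.42 (SE 0.23), Col6a3 by 1.08 (SE 0.21) and Col3a1 by 0.9 (SE 0.16). Of 33 matrix genes 9 fell, 24 did not pass, and 20 fell over the list alone, with a median of -0.56 (camera adjusted p = 7.99e-20; adjusted p = 0.0493 with an estimated correlation). Pericyte and smooth muscle genes fell in 2 of 14 members, Pdgfrb by 0.64 (SE 0.12) and Notch3 by 1.15 (SE 0.22), with 4 over the list alone (camera adjusted p = 3.3e-07; adjusted p = 0.122 with an estimated correlation). Markers of other cells were lower beside them with 0 past the test, fibroblast and perineurium genes with a median of -0.5 over 16 (camera adjusted p = 7.71e-05; adjusted p = 0.122 with an estimated correlation) and endothelium genes with -0.42 over 16 (camera adjusted p = 0.000278; adjusted p = 0.216 with an estimated correlation).

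Tubb3, a tubulin of neurons, rose from 2360 ± 302 to 3260 ± 321 CPM (log2 fold change 0.47, SE 0.11, adjusted p = 0.0246) as 1 of 19 sensory neuron genes, with 9 over the list alone (camera adjusted p = 2.13e-07; adjusted p = 0.0306 with an estimated correlation). Of 22 glycolysis and polyol genes 3 rose and 13 over the list alone, among them the pyruvate kinase gene Pkm by 0.38 (SE 0.09) and the glucose transporter gene Slc2a3 by 0.42 (SE 0.09) (camera adjusted p = 4.97e-10; adjusted p = 0.0306 with an estimated correlation). Of 41 oxidative phosphorylation genes 4 rose and 8 over the list alone, among them Ndufv1 by 0.41 (SE 0.08) and Uqcrc1 by 0.35 (SE 0.08) (camera adjusted p = 2.91e-08; adjusted p = 0.216 with an estimated correlation), and the median of 0.14 was 0.05 to 0.28 with 1 library left out. Of 23 unfolded protein response genes 2 rose, Hspa5 by 0.59 (SE 0.1) and Atf3, with 4 over the list alone (camera adjusted p = 3.3e-07; adjusted p = 0.0306 with an estimated correlation). Of 18 heat shock genes Stip1 rose by 0.36 (SE 0.09), with 12 over the list alone (camera adjusted p = 1.03e-07; adjusted p = 0.0493 with an estimated correlation).

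Injury and pain genes changed in part. Atf3 rose from 10.5 ± 4.5 to 40.6 ± 32.1 CPM (log2 fold change 1.96, SE 0.45, adjusted p = 0.0329), with 56.9 and 89.6 CPM in 36-week replicates 1 and 2 and 15.6 to 23.1 in the other 3, and Tubb3 was the other of 24 neuronal injury genes to rise, with 13 over the list alone (camera adjusted p = 4.97e-10; adjusted p = 0.0707 with an estimated correlation). Trpv1, the capsaicin receptor of pain neurons, rose by 0.76 (SE 0.19) and Ntrk3 fell by 0.9 (SE 0.18), as the 2 of 30 nociception genes that passed. Bdnf, a neurotrophin, rose by 0.73 (SE 0.16), the secreted neuropeptide precursor gene Vgf by 0.75 (SE 0.18), Crtac1 by 0.76 (SE 0.16) and the galectin gene Lgals3 by 0.83 (SE 0.21). The chemokine gene Ccl8 had 1 count in 6 libraries at 12 weeks and 172 in 5 libraries at 36 weeks, a ratio of 180 (interval 31.8 to 7130, adjusted p = 0.0125).

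Clock genes fell, 3 of 19 tested, with 8 lower and 1 higher over the list alone (camera adjusted p = 3.97e-06; adjusted p = 0.0306 with an estimated correlation). Per3 fell by 1.38 (SE 0.22), Hlf by 1.03 (SE 0.25) and Dbp by 0.87 (SE 0.17), from 24.7 ± 5.33 to 13.5 ± 2.08 CPM. Of 18 glucocorticoid targets Klf15 fell by 1.04 (SE 0.23) and Sgk1 by 0.73 (SE 0.15), with 7 over the list alone (camera adjusted p = 1.06e-06; adjusted p = 0.0843 with an estimated correlation). Of 22 myelin genes 0 passed, 14 were lower and 1 higher over the list alone, and the median was -0.52 (camera adjusted p = 6.65e-12; adjusted p = 0.122 with an estimated correlation). Schwann identity genes, a list added after the counts were seen, were lower beside them, 3 of 16 tested, with 7 lower and 1 higher over the list alone and a median of -0.22 (unadjusted camera p = 5.25e-06; unadjusted p = 0.00213 with an estimated correlation). Insr, the insulin receptor, fell by 0.54 (SE 0.12). Of 24 cholesterol synthesis genes 0 passed, with a median of 0.12 (camera adjusted p = 0.000685; adjusted p = 0.156 with an estimated correlation).

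Chil3 fell from 6.09 ± 9.64 to 0.159 ± 0.162 CPM (log2 fold change -5.26, SE 1.2, adjusted p = 0.0276), the neutrophil gene S100a8 from 18.1 ± 23.2 to 1.05 ± 0.642 (-4.1, SE 0.83) and the lipid droplet gene Plin4 from 4.58 ± 3.01 to 0.661 ± 0.371 (-2.79, SE 0.53). At 12 weeks S100a8 ranged from 2.7 to 58.2 CPM between libraries. It was the 1 of 12 lymphocyte and neutrophil genes to pass, with 5 lower over the list alone (camera adjusted p = 0.000701; adjusted p = 0.216 with an estimated correlation), and the median of -1.76 was -1.12, -1.08 and -1.1 without 36-week replicates 3, 4 and 5. Plin4 was the 1 of 16 adipocyte genes to pass, with 2 lower over the list alone and no call by camera (adjusted p = 0.0544). Rn45s took 11.6 ± 3.38% of counts at 12 weeks and 4.85 ± 1.13% at 36 weeks, and this difference accompanies each gene group above. Skeletal muscle genes had a median of -3.19 (camera adjusted p = 0.0048), and lost their call without 12-week replicate 1 (median -1.22, adjusted p = 0.28). Erythrocyte genes had -1.55 (camera adjusted p = 0.00784, and 0.0889 without the same replicate) and satellite glia genes -0.17 (0.00321). Of the 30 named genes that passed, 13 passed with any 1 library left out, and the other 17 were Atf3, Lgals3, Trpv1, Vgf, Chil3, S100a8, Uqcrc1, Pkm, Slc2a3, Bdnf, Tubb3, Ntrk3, Hlf, Sgk1, Klf15, Insr and Stip1. Without 36-week replicates 1, 2, 3, 4 and 5, those lost numbered 11, 17, 8, 10 and 6 (adjusted p up to 0.134, 0.151, 0.0932, 0.148 and 0.092). Without 12-week replicates 1, 2, 3, 4, 5 and 6 they numbered 2, 8, 12, 3, 4 and 1 (adjusted p up to 0.077, 0.0986, 0.107, 0.0748, 0.0667 and 0.0662). The count was 42, 63, 74, 97 and 120 without 36-week replicates 2, 3, 4, 5 and 1, and 75, 99 and 329 without 12-week replicates 3, 2 and 6. With a log2 fold of at least 1, 18 of the 30 lost a call. Under settings of normalization, filter, test, covariate or libraries in the fit 12 did, among them Atf3, Lgals3, Trpv1 and S100a8 with only the compared groups (adjusted p up to 0.0851), Atf3, Lgals3 and Vgf by limma voom (up to 0.228), Atf3, Lgals3, Vgf, Chil3 and Hlf with the muscle covariate (up to 0.0766), and Trpv1, Crtac1, Vgf, Chil3, Pkm, Slc2a3, Bdnf and Tubb3 with both tissues in 1 fit (up to 0.648). Ccl8 was not tested under 3 settings.

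The diet by tissue interaction tested whether the diet difference was the same in nerve and ganglia. At 12 weeks 2 genes passed, 1 of them with a predicted name, and 1382 had an unadjusted p under 0.05, while DESeq2 called 74 and limma voom 1. Prr32 was the other, with 650 counts in the 6 high-fat diet nerve libraries and 0 in the 6 standard diet ones (adjusted p = 0.00285). Fasn had a log2 difference of -1.29 (SE 0.27), Acsbg1, an acyl-CoA synthetase, 0.93 (SE 0.19) and Ntrk3 0.95 (SE 0.2), each with an adjusted p of 0.0653. Vmn1r181 and Nxnl1 had the same adjusted p, with few counts in ganglia. Of 22 fatty acid and triglyceride synthesis genes 0 passed and 6 were lower over the list alone (camera adjusted p = 5.99e-09; adjusted p = 0.0829 with an estimated correlation), and their median of -0.36 was -0.23 without nerve standard diet replicate 4. With only the compared groups in the fit 0 genes passed (adjusted p = 0.632 for Prr32). The count was 1 without nerve standard diet replicates 1 and 5, nerve high-fat diet replicates 3 and 6, ganglia standard diet replicate 5 and ganglia high-fat diet replicates 3 and 6. It was 4 without ganglia standard diet replicate 4 or high-fat diet replicate 2, and 5 without nerve high-fat diet replicate 1 or ganglia high-fat diet replicates 4 and 5. It was 6 without ganglia standard diet replicate 6 or high-fat diet replicate 1, 7 without nerve standard diet replicate 6, and 10 without nerve high-fat diet replicates 2 and 5.

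At 36 weeks 27 genes had a more positive and 3 a more negative diet difference in nerve than in ganglia, with 1070 at an unadjusted p under 0.05. The log2 difference was 10.64 (SE 2.11) for Itgad, 9.29 (SE 1.5) for Tph2, 5.83 (SE 1.12) for Slc5a7, 4.95 (SE 1.12) for Tmem132b and 4.01 (SE 0.79) for Oxtr (adjusted p = 0.012, 0.000975, 0.00999, 0.0419 and 0.012). Stmn4 had -3.11 (SE 0.7, adjusted p = 0.0419). The collagen gene Col19a1 and Ush1g, a scaffold gene of hair cells, had 0 counts in high-fat diet nerve and 274 and 88 in standard diet nerve, at least 111-fold and 35.5-fold lower there by counting alone. Their difference between tissues passed (interaction adjusted p = 0.0196 and 0.0183), while within nerve Col19a1 did not pass (adjusted p = 0.0652) and Ush1g had too few counts to be tested. Angptl4 had 1.57 (SE 0.35, adjusted p = 0.0419) and Atf3 2.2 (SE 0.52, adjusted p = 0.0553). The genes Plin2, a lipid droplet coat protein (1.55, SE 0.25), Ctsd (0.78, SE 0.126) and Mest (2.90, SE 0.508) also passed and were chosen after their values were seen.

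Antigen presentation genes had a median difference of 0.55 over 17 members with 0 past the test (camera adjusted p = 1.27e-07; adjusted p = 0.361 with an estimated correlation). Fatty acid oxidation and PPAR genes had 0.18 over 26 (camera adjusted p = 0.000189; adjusted p = 0.361 with an estimated correlation). Skeletal muscle genes had -6.61 over 20, with 18 lower over the list alone (camera adjusted p = 0.00105; adjusted p = 0.774 with an estimated correlation), and lost their call without nerve standard diet replicate 4 (median -0.16, adjusted p = 0.704) and ganglia high-fat diet replicate 2 (median -3.09, adjusted p = 0.0599). Of the 12 named genes that passed, 7 passed with any 1 library left out. Tmem132b passed in 2 of 22 such fits (highest adjusted p 0.0891, without nerve standard diet replicate 3), Angptl4 in 3 (0.106, without ganglia standard diet replicate 1) and Stmn4 in 5 (0.116, without nerve standard diet replicate 2). Itgad had an adjusted p of 0.83 without ganglia standard diet replicate 3, and Ush1g 0.133 without nerve standard diet replicate 2. Col19a1, Ush1g and Stmn4 lost their call by limma voom (adjusted p up to 0.369), Ush1g and Stmn4 with only the compared groups (up to 0.0961), Angptl4 with the muscle covariate (0.0534), and Ctsd with a log2 fold of at least 1.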

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

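In this part, the test of whether adipocyte markers rise alike and the fits without the libraries in doubt were chosen after the result was seen. Genes whose diet response differed between ages or tissues come first, then single libraries that lay far from the others of their group, then 3 patterns that were weighed.

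The diet response of the sciatic nerve differed between 12 and 36 weeks by the interaction test in 1 gene, Pgd, with a log2 difference of 0.91. Between nerve and ganglia it differed in 2 genes at 12 weeks, among them Prr32 with a fitted difference of 10.08, and in 30 genes at 36 weeks. Those named were Itgad (10.64), Tph2 (9.29), Slc5a7 (5.83), Tmem132b (4.95), Oxtr (4.01), Col19a1 (-8.74), Ush1g (-7.43) and Stmn4 (-3.11). The fitted differences of Prr32, Col19a1 and Ush1g, each with 0 counts in a nerve group, are no bounds.

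A gap test found 8 libraries far from their group in 96 sets of 5 or 6 libraries, where chance alone gives about 1 in 20, or 4.8. In nerve, Itgax was at 3.52 CPM in replicate 2 of the 12-week high-fat diet group (others 0.294 to 1.32). In ganglia, Atf3 was at 29.6 CPM in replicate 3 of the 12-week high-fat diet group (others 8.81 to 15.5) and at 27.9 CPM in replicate 4 of the 36-week high-fat diet group (others 7.44 to 13.7).

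The muscle score was 6.89 in replicate 1 of the 12-week standard diet nerve (others -0.64 to 0.88) and 9.83 in replicate 4 of the 36-week standard diet nerve (others -0.44 to 1.8). The adipocyte score was 0.8 in replicate 5 of the 12-week high-fat diet nerve (others 5.24 to 7.07). Replicate 6 of the 36-week high-fat diet nerve had 52.6 M counts (others 32.5 to 39.2), and replicate 4 of the 12-week high-fat diet ganglia had counts for 13119 genes (others 15144 to 16282).

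Splits of the same libraries into other groups, 100 per comparison with the real one, showed how often other groupings called as many genes. The smallest share they can give is 1 in 100, and 10 comparisons were judged. A low share therefore makes chance less likely without excluding it. As many genes as the 101 of the 36-week nerve diet comparison came from 1 split, the real one (highest other 1), as many as the 207 of the nerve age comparison from 1 (highest other 2), and as many as the 30 of the tissue interaction at 36 weeks from 1 (highest other 2). The 1 gene of the nerve diet by age interaction came from 1 split (highest other 0), the 2 of the 12-week nerve diet comparison from 4 (highest other 35) and the 188 of the ganglia age comparison from 2 (highest other 256). Chance readily gave as many genes as the 1 of the 12-week ganglia diet comparison (19 splits, highest other 1990) and the 2 of the tissue interaction at 12 weeks (30 splits, highest other 305). With 0 genes, the diet comparison at 36 weeks and the interaction with age in ganglia were matched by 100 of 100 splits (highest other 1 in each). Splits that called 1990, 305 or 35 genes, several times the real count, point to a structure of the samples other than diet, and in the ganglia age comparison 1 other split called more genes than the real one (256 against 188).

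The first pattern weighed was the 92 genes higher on the high-fat diet in 36-week nerve. More adipocytes in those samples were argued against only as far as the adipocyte score measures them. The median log2 fold change of the 92 genes was 0.62 and stayed 0.61 with that score as a covariate, with 92 still called. The score averages members that moved apart (12 positive and 8 negative of 20), and its lowest value came from 12-week high-fat diet replicate 5 (0.8). Adipoq, chosen after its values were seen, stood at 638 ± 134 (n = 6) against 321 ± 139 CPM (n = 5). More adipocytes are therefore not ruled out. Adipocyte markers moved apart when adjusted over the list alone, 1 lower (Cfd) and 1 higher (Lep). Skeletal muscle in the standard diet samples was argued against by a median of 0.63 with the muscle covariate, with 77 still called. A changed state of fat tissue beside the nerve was not tested and stays open as a possible explanation, beside a response of the nerve itself to the diet.

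The second pattern was the fall of cholesterol synthesis genes with age in nerve on standard diet. A lower share of Schwann cells large enough to give this fall was argued against. The mean log2 CPM of 16 Schwann identity genes differed by -0.08 (SE 0.12, two-sided exact p = 0.494, n = 5 and 6). The cholesterol score differed by -1.04 (SE 0.11). The Schwann identity list was added after the counts were seen. Its median log2 fold change was -0.15, with 4 of 16 members positive (unadjusted camera p = 0.0199; unadjusted p = 0.446 with an estimated correlation). A small fall in the share of Schwann cells is therefore not excluded. Dilution by adipocytes was argued against only as far as the adipocyte score measures them. The list median was -1 with that score as a covariate (-1.05 without it), with 21 members called. The lowest value of the score came from 12-week high-fat diet replicate 5 (0.8), a library outside this comparison. Clock phase at collection and a biological change with age cannot be told apart. Within groups, the clock gene Dbp and the cholesterol score had a Pearson r of -0.29 (two-sided permutation p = 0.221, n = 23; Spearman rho -0.24), and collection times were not given in the sources used here.

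The third pattern was the small number of diet genes in 12-week ganglia. That 2 libraries of low yield or high ribosomal RNA hid a diet difference was argued against, since without both libraries 1 gene was called, as with them. The splits with up to 1990 genes show that the 12 libraries differ from one another along some other line, whose cause was not tested. A diet response in fewer cells than bulk RNA resolves was not tested.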

How the results depend on the processing

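Fits without the libraries in doubt and without Rn45s and Lars2 were chosen after the data were seen; the other alternatives were planned. Of the results of named genes over the refits, 3673 kept their direction and side of the threshold, 375 lost their call, 129 gained one and 0 reversed. These totals leave out the least log2 fold change of 1 and any setting in which a gene was not tested. Of the called lists, over settings other than 1 library left out, 519 kept theirs, 271 lost theirs and 8 reversed.

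The diet count at 12 weeks in nerve (2) became 1 with a log2 fold of at least 1, 1 with the replicate block, 27 with the adipocyte covariate, 5 without the libraries in doubt, 20 by DESeq2, 0 with only the compared groups and 29 with both tissues in 1 fit. At 36 weeks (101) it became 27 with a log2 fold of at least 1, 224 with the adipocyte covariate, 210 by DESeq2, 224 by limma voom, 153 with only the compared groups and 219 with both tissues. The interaction with age in nerve (1) became 0 with a log2 fold of at least 1, 4 with the block, 4 with the adipocyte covariate, 0 without the libraries in doubt, 33 by DESeq2, 8 by limma voom and 52 with both tissues. The age count in nerve (207) became 37 with a log2 fold of at least 1 and 320 by DESeq2.

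The diet count at 12 weeks in ganglia (1) became 0 with the strict filter, the block, the muscle covariate, limma voom or only the compared groups, 29 by DESeq2 and 10 with both tissues. At 36 weeks (0 by edgeR, 158 at an unadjusted p under 0.05, 0 by DESeq2) it became 21 by limma voom. The interaction with age in ganglia (0 by edgeR, 519 at an unadjusted p under 0.05) became 3 by DESeq2 and 1 with both tissues, and stayed 0 by limma voom. The age count in ganglia (188) became 31 with a log2 fold of at least 1, 633 without the libraries in doubt, 571 by DESeq2, 934 by limma voom, 339 with only the compared groups and 388 with both tissues. The ganglia libraries in doubt lie outside the groups of this comparison, so they act on its count only through the shared fit.

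The tissue interaction at 12 weeks (2) became 0 with the block, 19 with the adipocyte covariate, 74 by DESeq2, 1 by limma voom and 0 with only the compared groups. At 36 weeks (30) it became 9 with the block, 48 with the adipocyte covariate, 58 without the libraries in doubt, 90 by DESeq2, 146 by limma voom and 110 with only the compared groups. The lists called over the 4 diet comparisons (45) became 1 with an estimated correlation and 2 by fry. Beyond that shared fit for the ganglia age count, the cause of these changes was not tested.

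Leaving out 1 library at a time, the counts ranged from 1 to 8 (diet at 12 weeks in nerve), 61 to 99 (36 weeks), 0 to 14 (interaction with age) and 133 to 297 (age). In ganglia they ranged from 0 to 2, 0 to 0, 0 to 0 and 42 to 329 in the same order, and between tissues from 1 to 10 at 12 weeks and 20 to 37 at 36 weeks.

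The direction of 8 lists reversed, with these camera adjusted p values under the alternative. Without the libraries in doubt, skeletal muscle genes reversed in the nerve diet comparison at 36 weeks (0.139), the interaction with age (0.00435) and the age comparison (0.0963), the last together with oxidative phosphorylation (0.832); the alternative removes the library with the highest muscle score. With the muscle covariate they reversed in ganglia at 12 weeks (0.656), 36 weeks (0.55) and the interaction with age (0.472), as that covariate is their own score. Myelin genes reversed in the nerve interaction with age under the adipocyte covariate (0.681), and the cause was not tested.

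Whether libraries with the same replicate number share a mouse stays open, and the numbers were not used as pairs: correlations between samples of the same number exceeded 0.1 in 4 of 22 pairs across diets, 4 of 23 across tissues and 2 of 10 across ages. Between nerve and ganglia at 36 weeks on high-fat diet they were 0.054 to 0.184 in the 6 pairs, with 3 above 0.1 and 4 samples closest to their own number, a hint from the data.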

Other observations

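In 36-week sciatic nerve on the high-fat diet, genes of lipid-laden macrophages and of lysosomes rose. Plin2, which coats lipid droplets, went from 63.8 ± 16 (n = 5) to 173 ± 31.6 CPM (n = 6), and Ctsd, the lysosomal cathepsin D, from 613 ± 50.8 to 1030 ± 116 (log2 fold changes 1.44 and 0.75, adjusted p = 0.00217 and 0.000112). Lgals3, a galectin of phagocytes, rose by 0.98, the lysosomal hydrolase gene Gusb by 0.73, the cholesterol exporter gene Npc2 by 0.58 and the acid lipase gene Lipa by 0.55 (adjusted p = 0.00735, 0.00173, 0.000964 and 0.00562). Trem2, a lipid receptor of macrophages, stood at a log2 fold change of 0.94 without passing (adjusted p = 0.294). These genes and the 2 lists below were chosen after the values were seen, and the tests of the lists on members that had not been called were chosen before those members' values were seen.

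Of 22 tested lipid-associated macrophage genes 6 rose, with 9 over the list alone and 20 positive, and of 51 lysosomal genes 8 rose, with 18 over the list alone and 44 positive. The 16 macrophage genes that had not been called had a median log2 fold change of 0.59 and the 43 lysosomal ones 0.13, each at percentile 100 of the medians of 10000 random lists. Those lists drew single genes matched on expression, so the percentile ignores correlation between members and does not measure variation between libraries. The macrophage list fixed beforehand was not called in this comparison (17 tested, 0 past the test, median 0.17, camera adjusted p = 0.115). This is consistent with a candidate explanation in which lipid-associated macrophages were more numerous, or more active, in the high-fat diet samples, without a shown rise of macrophage genes at large. Whether such cells lay in the nerve or in fat around it was not tested, and Mmp12 and Itgax, the members with the largest rises named in the report, lost their calls in most fits with 1 library left out. Other immune lists were called with 0 members past the test, cytokines and chemokines (median 0.47, camera adjusted p = 0.00494), lymphocyte and neutrophil genes (1.24, 0.0177) and complement genes (0.18, 0.0355). With an estimated correlation their adjusted p was 0.43, 0.43 and 0.749. The last 2 lists lost their call in 5 and 6 of 11 fits with 1 library left out.

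Lipf, a lipase gene chosen after its values were seen, had 1241 counts in 6 of 6 high-fat diet nerve libraries and 0 in 5 standard diet libraries at 36 weeks, at least 342-fold higher (adjusted p = 0.00956). At 12 weeks it had 120 counts in 3 of 6 high-fat diet libraries and 0 in 6 standard diet libraries. Pgd rose by 0.62 at 36 weeks (adjusted p = 0.00263).

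The alpha and beta globin genes are listed with 1 count (Hba-a1) or 0 (Hba-a2, Hbb-bs and Hbb-bt) over the 46 libraries, while the erythroid gene Alas2 had 6398, so that blood could not be measured from globin here.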
